A study of Mus musculus with 6 samples.

How the data were processed

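The series measured polyadenylated RNA in 6 mouse samples by RNA sequencing. The samples fell into 3 groups of 2 libraries: cells that an antibody to NG2 had sorted out of skeletal muscle, osteosarcomas, and soft tissue sarcomas, all from NG2-Cre;p53flox/flox animals of mixed background. Per the labels' protocols, RNA was extracted with Trizol, about 10 ng of each sample was copied into cDNA from an oligo(dT) primer with template switching, the cDNA was amplified in 20 PCR cycles, and paired-end libraries were prepared from it. Amplified reads without molecular identifiers are not independent molecules, so every interval and floor based on counts covers counting error only.

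The deposited values were raw read counts per Ensembl gene, whole numbers in 1 table per library, with 5 counters for reads that were not assigned to a gene at the end of each table. Per the submitters' processing notes, Trim Galore, cutadapt, FastQC, STAR, HTSeq and DESeq2 were used on the mouse builds GRCm38 and mm10; the notes gave no versions, settings or roles. The strand setting, the annotation release and the treatment of reads that match several genes were not stated, so counts of overlapping genes, antisense genes and near-identical copies were treated as uncertain. Of 38561 gene IDs, 36723 were found in the GENCODE M21 annotation of GRCm38, which gave the positions, and 36639 had a symbol. The 1922 IDs without a symbol held at most 0.304% of the counts of a library.

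From the deposited counts, differential expression was tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, low counts were filtered with filterByExpr by group (min.count 10, min.total.count 15), which left 19024 genes, and quasi-likelihood F tests compared the groups in 1 model of all 6 libraries without covariates. With 2 libraries per group, the model had 3 residual degrees of freedom, shared by the 3 groups, and the tests used 3.04 prior degrees of freedom. The common dispersion was 0.334, a biological coefficient of variation of 0.578. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the verbs rose and fell are used for called genes. Normalised read counts (CPM) were scaled by the TMM factors, group values are means with the SD over 2 libraries, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. A fold against a group with 0 counts is given as a lower bound, computed with 3 counts over the group in place of 0, and where a group held 1 to 3 counts its CPM is given in place of a fold. A permutation test of 2 against 2 libraries cannot give a p under 0.333.

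The tests were also run on simulated counts, with the mean of each gene over all libraries and the library sizes and spread of the real ones. In them 100 genes changed by 4-fold and 100 by 16-fold. A first run of 1 draw per comparison was replaced by 10 repeats after the real data had been analysed. The reason was that a change of seed moved the recovery at 4-fold, in 1 draw to above all ranges given here. Over 10 repeats, 2 to 13 of the 100 genes at 4-fold and 53 to 74 of the 100 at 16-fold passed the threshold in the comparison of osteosarcoma with NG2 cells. For soft tissue sarcoma against NG2 cells these numbers were 1 to 10 and 60 to 72, and for soft tissue sarcoma against osteosarcoma 3 to 15 and 60 to 74. The sign was right for 95 to 100 of each 100 changed genes, and 1 to 10 unchanged genes were called per comparison and repeat. Far fewer genes changed in the simulations than were called in the real comparisons with NG2 cells (4086 and 3671). The adjusted threshold depends on that share, so the recoveries do not measure the power of those comparisons.

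Before the data were examined, 25 gene lists were fixed: pericyte and mural cell, osteoblast and bone matrix, chondrocyte, osteoclast, fibroblast, skeletal muscle fibre, myogenic progenitor, adipocyte, endothelial, macrophage, lymphocyte, granulocyte and erythroid, and Schwann cell and glia markers, then Wnt/beta-catenin targets, secreted Wnt antagonists, Wnt ligands and receptors, TGF-beta and BMP targets, p53 targets, cell cycle, matrix remodelling, immediate early and heat shock, hypoxia and glycolysis, interferon response, mitochondrially encoded genes and the Hox clusters. Each list was tested against all other tested genes with camera (limma 3.58.1) at its preset correlation of 0.01, and p was adjusted over the 75 tests of 3 comparisons. The choice of the model, the filter, the lists, most of the alternatives and the genes to be named was also made before the data were examined. The rule named Trp53, Cspg4 and Ctnnb1; per comparison the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes whose libraries did not overlap, with a mean of at least 20 CPM in the higher group and at least 10 counts in the lower one; up to 4 members of each list in order of p; a short list of cell type and pathway genes; and Xist with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Other genes are named as chosen after their values were seen.

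Both tumour types were compared with the same 2 control libraries. The agreement of their log2 fold changes was therefore set beside 20 simulations of unchanged tumours that shared the controls, and the overlap of their calls beside that of independent lists. The alternatives were DESeq2's size factors, total counts, no filter, a filter of at least 50 counts, removal of mitochondrial and haemoglobin genes, the replicate number as a block, a model of only the 2 groups compared, DESeq2 1.42.0, camera with an estimated correlation, and leaving out each library in turn. Removal of immunoglobulin genes, removal of 4 genes of low counts from the mitochondrial list, the newer quasi-likelihood method of edgeR, and DESeq2 counts for each left-out library were added after the data had been seen. The 5 counters of unassigned reads were used only to describe the libraries.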

Results

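RNA was sequenced from 6 samples in 3 groups of 2 libraries, all from NG2-Cre;p53flox/flox mice. In these animals the Cre recombinase is driven by the promoter of Cspg4, the gene of the NG2 proteoglycan of pericytes, and removes a floxed part of the tumour suppressor gene Trp53. The first group was cells sorted from skeletal muscle with an antibody to NG2 (NG2 cells). The second group was osteosarcomas, replicate 1 from the right tibia and replicate 2 from the lumbar spine, and the third was subcutaneous soft tissue sarcomas. Reads counted on genes came to 39453073 and 44622315 in the NG2 cell libraries, 52056569 and 28107779 in osteosarcoma, and 58126832 and 27693585 in soft tissue sarcoma. The labels did not say whether each library came from a separate animal, so the p-values measure the spread between these samples. The flow cell lane in the deposited names was 4 for both NG2 cell libraries, 5 for both osteosarcomas and 6 for both soft tissue sarcomas, so a lane effect and the group cannot be told apart.

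Across genes, which are not independent replicates, the log2 CPM of replicates correlated with Pearson's r of 0.919 in NG2 cells, 0.908 in osteosarcoma and 0.958 in soft tissue sarcoma. Between NG2 cells and tumours r lay between 0.696 and 0.77, and between the tumour types it lay between 0.866 and 0.875. Reads that overlapped no annotated gene made up 33.2% of both NG2 cell libraries and 19.5% to 23.4% of the tumour libraries. Immunoglobulin genes held 0.974% and 5.1% of the counts of the NG2 cell libraries and at most 0.00909% of a tumour library. The mitochondrial chromosome held 4.55% and 4.38% in NG2 cells, 2.51% and 3.78% in osteosarcoma, and 2.15% and 2.26% in soft tissue sarcoma. The widest 95% Wilson interval of these shares was 0.0261 percentage points.

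Trp53 (ENSMUSG00000059552; chromosome 11, 69580359 to 69591873, GRCm38), the floxed gene, had 101 and 82.3 CPM in NG2 cells, 24.3 and 32.6 CPM in osteosarcoma, and 31.2 and 27.3 CPM in soft tissue sarcoma. It fell by 1.69 ± 0.30 on the log2 scale in osteosarcoma (SE, n = 2 per group; edgeR adjusted p = 0.0172) and by 1.65 ± 0.30 in soft tissue sarcoma (adjusted p = 0.0199). Counts of the whole gene include exons outside the floxed part, so they check the deletion only weakly, and the NG2 cells carried the same alleles. The NG2 cell libraries also held transcripts of other cell types, such as those of immunoglobulin genes. The falls of Trp53 can therefore not be separated from a difference in cell types. Cspg4 (ENSMUSG00000032911; chromosome 9, 56865033 to 56899870), which encodes NG2, had 38.6 and 30.6 CPM in the cells sorted for NG2, 118 and 37.7 CPM in osteosarcoma, and 188 and 88.7 CPM in soft tissue sarcoma (adjusted p = 0.212 and 0.0731). Ctnnb1 (ENSMUSG00000006932; chromosome 9, 120929216 to 120960507), the gene of beta-catenin, the transducer of canonical Wnt signals, had 79.6 and 154 CPM in NG2 cells, 584 and 487 CPM in osteosarcoma, and 187 and 152 CPM in soft tissue sarcoma. Ctnnb1 rose 4.58-fold in osteosarcoma (log2 fold change 2.20 ± 0.39, adjusted p = 0.0174). In soft tissue sarcoma its log2 fold change was 0.54 ± 0.37 (adjusted p = 0.337), and the difference between the tumour types, a log2 fold change of -1.66 ± 0.38, did not pass the threshold (adjusted p = 0.143).

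**Figure D1:**
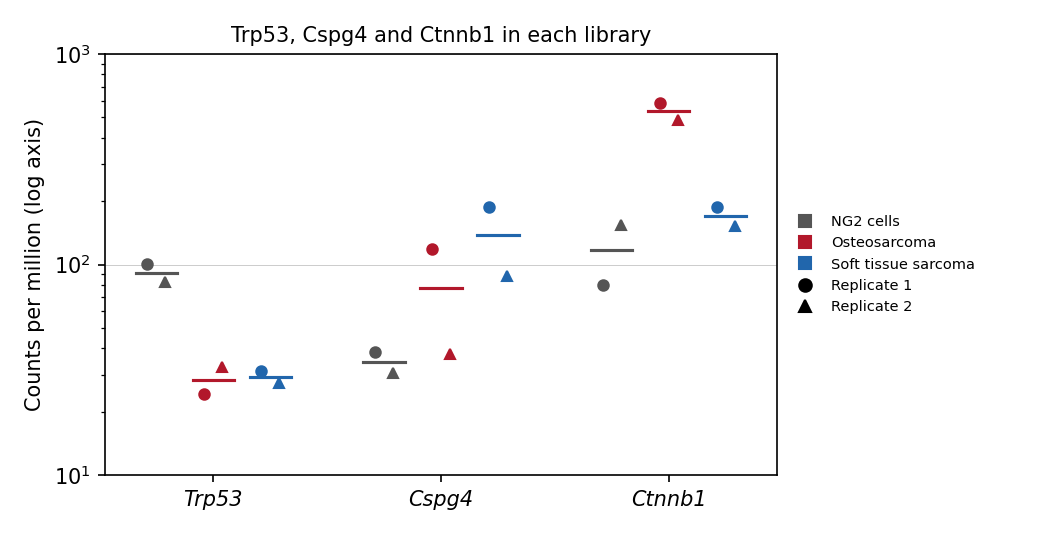
CPM (normalised read counts, log axis) of Trp53, Cspg4 and Ctnnb1 in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2 and a bar for the mean of 2 libraries. Both tumour types lay below the NG2 cells for Trp53 (24.3 to 32.6 CPM against 82.3 and 101 CPM), and both osteosarcomas lay above all other libraries for Ctnnb1 (487 and 584 CPM).

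Xist, the RNA that coats the inactive X chromosome of female cells, had 347 and 488 CPM in NG2 cells, 54.2 and 204 CPM in osteosarcoma, and 0.0839 and 0.135 CPM in soft tissue sarcoma. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were between 7.62 and 76.7 CPM in both soft tissue sarcoma libraries and at most 0.0711 CPM in the NG2 cell libraries and osteosarcoma replicate 2. Osteosarcoma replicate 1 had both, with Ddx3y at 14.8 CPM and Xist at 54.2 CPM. Soft tissue sarcoma and NG2 cells differed in these genes in both libraries of each group, so a difference in sex and the group cannot be told apart there. Between the tumour types the same limit holds for Xist, which both osteosarcomas had and both soft tissue sarcomas nearly lacked. The osteosarcoma libraries differed from each other in the Y-linked genes. Of the 3671 genes called in soft tissue sarcoma against NG2 cells, 101 lay on the X chromosome, which held 676 of the 19024 tested genes, and 1 on the Y chromosome, which held 6.

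**Figure D2:**
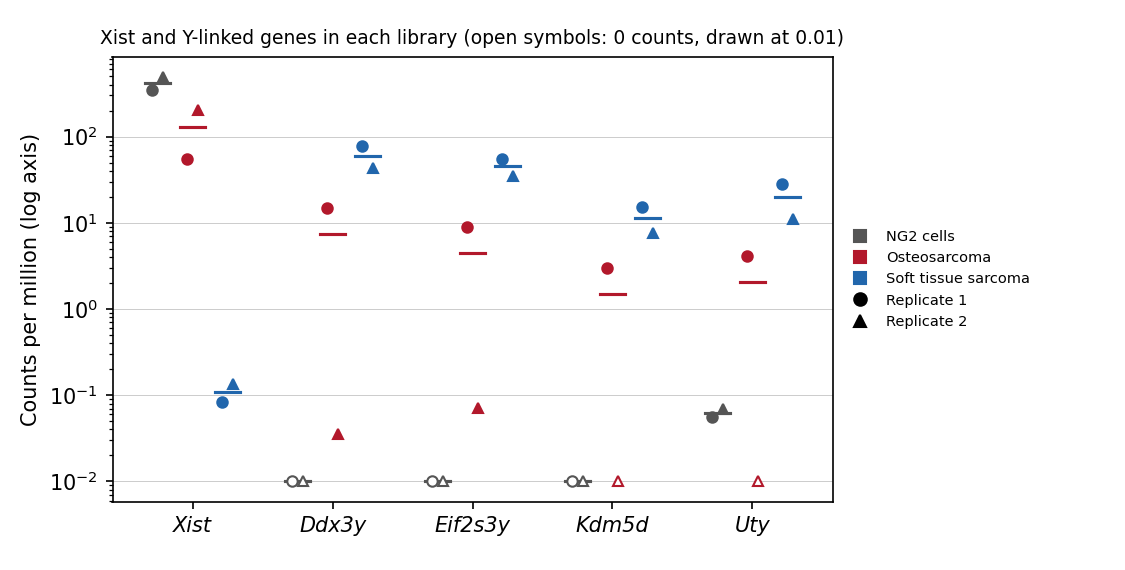
CPM (normalised read counts, log axis) of Xist and 4 Y-linked genes in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2, bars for means, and open symbols for libraries at 0 counts. Osteosarcoma replicate 1 carried Ddx3y at 14.8 CPM beside Xist at 54.2 CPM, while the soft tissue sarcomas had at most 0.135 CPM of Xist.

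Osteosarcomas were compared with NG2 cells to describe how the bone tumours differed from the cells sorted with the NG2 antibody. Among the genes that met the naming rule, which asks for at least 10 counts in the lower group, the largest rises included Mmp13 (ENSMUSG00000050578; chromosome 9, 7272514 to 7283331), a collagenase of bone, which reached 14510 ± 13120 CPM (SD, n = 2) against 0.291 ± 0.411 CPM, and Col1a1 (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042), the main collagen chain of bone, which reached 25900 ± 8911 CPM against 30.2 ± 15.6 CPM, 858-fold. Bglap, which encodes osteocalcin and shares reads with near-identical copies, rose by a log2 fold change of 11.75 ± 2.19 (SE). Ctsk and Ocstamp, genes of bone-resorbing osteoclasts, rose as well, but from very unequal libraries: Ctsk had 276 and 6020 CPM in osteosarcoma replicates 1 and 2. The largest falls under this rule included genes of B cells and other immune cells: Ccr7 (ENSMUSG00000037944; chromosome 11, 99144196 to 99155077), a chemokine receptor, fell from 2588 ± 1507 to 0.231 ± 0.327 CPM, and Cd79a, a chain of the B cell receptor, from 1197 ± 952 to 0.246 ± 0.0537 CPM. When each library was left out in turn, the log2 fold changes ranged from 14.15 to 16.38 for Mmp13, 9.29 to 10.40 for Col1a1, 7.67 to 12.70 for Bglap, 5.90 to 10.32 for Ctsk, 6.36 to 11.11 for Ocstamp, -14.16 to -12.49 for Ccr7 and -12.90 to -11.07 for Cd79a. Fits that left at most 3 counts in a group are not in these ranges, here and below.

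Other genes among the largest rises under the rule were Slc9b2 and Cgref1, at log2 fold changes of 9.37 ± 1.98 and 8.99 ± 1.64. The remaining largest falls under the rule were Fcer2a, Cxcl2, H2-Ob, Fosb, Tnfrsf13c and Ccl22, with log2 fold changes between -11.33 for Fcer2a and -9.28 for Ccl22. Fcer2a, H2-Ob and Tnfrsf13c are B cell genes, Cxcl2 and Ccl22 are chemokines, and Fosb is an immediate early transcription factor. Over the fits without 1 library, log2 fold changes ranged from 6.60 to 10.22 for Slc9b2, 7.95 to 9.50 for Cgref1, -11.96 to -10.22 for Fcer2a, -11.10 to -9.23 for Cxcl2, -11.05 to -9.75 for H2-Ob and -10.20 to -8.12 for Tnfrsf13c.

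Lists of skeletal and matrix genes were called as higher, with unequal shares of called members. Of the 25 tested osteoblast and bone matrix genes, 22 rose and 3 did not pass, and 24 rose when adjusted over the list alone. The osteoblast and bone matrix list had a median log2 fold change of 7.46 (adjusted p = 2.62e-19, and adjusted p = 0.299 with an estimated correlation). Col1a2 rose 310-fold, Sparc 34.3-fold and Alpl, the bone alkaline phosphatase, 34.5-fold, while Sp7 and Runx2, transcription factors of bone formation, reached 109 ± 34.95 CPM against 0.0831 ± 0.118 CPM and 316 ± 154 CPM against 47.1 ± 18.8 CPM. In the chondrocyte list 4 of 14 genes rose and 10 did not pass, with 5 higher when adjusted over the list alone. The chondrocyte list had a median log2 fold change of 2.27 (adjusted p = 0.0386, and adjusted p = 0.438 with an estimated correlation). Col2a1, the collagen of cartilage, had 0 counts in NG2 cells and rose at least 877-fold, Acan at least 129-fold and Col11a1 251-fold. The osteosarcoma replicates 1 and 2 were unequal for Col2a1 (12.3 and 53.7 CPM) and Acan (1.88 and 7.86 CPM). Of 14 osteoclast genes, 6 rose and 8 did not pass, with 8 higher when adjusted over the list alone. The osteoclast list had a median log2 fold change of 4.04 (adjusted p = 0.0047, and adjusted p = 0.58 with an estimated correlation). Acp5, the acid phosphatase of osteoclasts, had 395 CPM in osteosarcoma replicate 1 and 7460 CPM in replicate 2, and Atp6v0d2 rose 114-fold. In the matrix remodelling list 16 of 26 genes rose and 10 did not pass, with 23 higher when adjusted over the list alone. The matrix remodelling list had a median log2 fold change of 5.75 (adjusted p = 2.32e-12, and adjusted p = 0.335 with an estimated correlation). Col5a2 rose 141-fold, Col5a1 214-fold and Bgn, a proteoglycan of matrix, 17.9-fold. The Hox clusters had 4 genes that rose, led by Hoxc8 (15.9-fold) and Hoxc6 (9.35-fold), 1 that fell and 23 that did not pass, with 4 higher when adjusted over the list alone. The Hox clusters list had a median log2 fold change of 1.65 (adjusted p = 0.0149, and adjusted p = 0.333 with an estimated correlation). With single libraries left out, log2 values ranged from 4.22 to 5.62 for Alpl, 9.34 to 10.71 for Sp7, 2.11 to 3.22 for Runx2, 2.56 to 6.77 for Acp5, 3.62 to 9.12 for Atp6v0d2, 6.53 to 7.55 for Col5a2 and 7.10 to 8.90 for Col5a1.

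Components of the Wnt pathway moved in both directions. Of 13 secreted Wnt antagonists, 3 rose, 1 fell and 9 did not pass, with 7 higher and 1 lower when adjusted over the list alone. The secreted Wnt antagonists list had a median log2 fold change of 2.40 (adjusted p = 0.0254, and adjusted p = 0.335 with an estimated correlation). Sfrp2, at 64.2 ± 11.9 CPM in osteosarcoma and 0 counts in NG2 cells, rose at least 1710-fold, Wif1 rose 85.8-fold and Dkk3 71.3-fold, with unequal osteosarcomas (341 and 59.0 CPM of Wif1, 49.6 and 233 CPM of Dkk3) and log2 fold changes of 4.60 to 8.99 and 4.65 to 6.84 when each library was left out in turn, and Sfrp5 fell 67.4-fold. Of 28 Wnt ligands and receptors, 7 rose, 1 fell and 20 did not pass, with the same numbers when adjusted over the list alone. The Wnt ligands and receptors list had a median log2 fold change of 2.48 (adjusted p = 0.00363, and adjusted p = 0.313 with an estimated correlation). Wnt4 rose 14.5-fold, Ryk 9.14-fold and Fzd8 5.88-fold, and Fzd4 fell 5.94-fold. Among 17 Wnt/beta-catenin targets, 4 rose, 1 fell and 12 did not pass, with 7 higher and 2 lower when adjusted over the list alone, and the list was not called (median 2.07; adjusted p = 0.191). The cell cycle gene Ccnd1 rose 9.10-fold, Lef1, which lymphocytes also express, fell 6.47-fold, and Axin2 was at 1.95 ± 0.911 against 3.05 ± 2.86 CPM (log2 fold change -0.65 ± 0.96, adjusted p = 0.653). Dkk1, a Wnt antagonist with 0 counts in NG2 cells, was at 26.5 ± 35.4 CPM in osteosarcoma (adjusted p = 0.0557). When each library was left out in turn, the log2 fold changes ranged from -8.59 to -5.18 for Sfrp5, -3.47 to -2.04 for Fzd4 and -3.31 to -2.28 for Lef1.

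The cell cycle list was called as higher, and the lists of p53 targets and of immediate early and heat shock genes as lower. Of 30 cell cycle genes, 19 rose and 11 did not pass, with 23 higher when adjusted over the list alone. The cell cycle list had a median log2 fold change of 2.23 (adjusted p = 9.95e-12, and adjusted p = 0.348 with an estimated correlation). Cdk1 rose 15.8-fold, Plk1 26.2-fold and Top2a 5.87-fold, and Mki67, the gene of the Ki-67 proliferation marker, 4.22-fold. Of 24 p53 targets, 1 rose, 9 fell and 14 did not pass, with 4 higher and 10 lower when adjusted over the list alone. The p53 targets list had a median log2 fold change of -1.20 (adjusted p = 0.0149, and adjusted p = 0.348 with an estimated correlation). The antiproliferative gene Btg2 fell 58.5-fold, the cell death gene Pmaip1 21.8-fold and the cell cycle inhibitor Cdkn1a 3.65-fold, Phlda3 rose 20.1-fold, and Mdm2 was at 49.8 ± 14.4 CPM against 85.96 ± 1.011 CPM (adjusted p = 0.113). Of 22 immediate early and heat shock genes, 21 fell and 1 did not pass, and all 22 were lower when adjusted over the list alone. The immediate early and heat shock list had a median log2 fold change of -4.69 (adjusted p = 1.2e-27, and adjusted p = 0.134 with an estimated correlation). Atf3 fell 128-fold, Junb 29.7-fold and Zfp36 34.2-fold. Only the NG2 cells had been sorted, and their libraries also held transcripts of lymphocytes and granulocytes. For the p53 targets and the immediate early and heat shock genes, sorting, other cell types and the group can therefore not be separated. Over the fits without 1 library, log2 fold changes ranged from 4.2 to 5.48 for Plk1, 1.95 to 2.96 for Top2a, 1.52 to 2.89 for Mki67, -5.11 to -4.02 for Pmaip1 and 3.72 to 5.43 for Phlda3.

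Markers of other cell types moved with the groups. Of 15 lymphocyte genes, 11 fell and 4 did not pass, with 13 lower when adjusted over the list alone. The lymphocyte list had a median log2 fold change of -8.12 (adjusted p = 7.95e-19, and adjusted p = 0.134 with an estimated correlation). Lck, a T cell kinase, fell 103-fold and Cd8a fell 1030-fold. Ptprc, which encodes the leukocyte antigen CD45, fell 23.2-fold. Of 16 granulocyte and erythroid genes, 7 fell and 9 did not pass, with 11 lower when adjusted over the list alone. The granulocyte and erythroid list had a median log2 fold change of -6.20 (adjusted p = 0.000792, and adjusted p = 0.357 with an estimated correlation). Ngp, a granule gene of neutrophil precursors, had 23.1 and 1300 CPM in NG2 cell replicates 1 and 2. Of 16 endothelial genes, 6 fell and 10 did not pass, with 9 lower when adjusted over the list alone. The endothelial list had a median log2 fold change of -1.82 (adjusted p = 0.000607, and adjusted p = 0.556 with an estimated correlation). Pecam1, an endothelial adhesion gene, fell 7.85-fold and Ptprb 14.4-fold. Of 11 Schwann cell and glia genes, 4 fell and 7 did not pass, with 5 lower when adjusted over the list alone. The Schwann cell and glia list had a median log2 fold change of -3.11 (adjusted p = 0.000583, and adjusted p = 0.348 with an estimated correlation). Mbp, a gene of a myelin protein, fell 11.3-fold. With single libraries left out, log2 values ranged from -10.36 to -9.52 for Cd8a, -13.76 to -7.89 for Ngp, -3.57 to -2.58 for Pecam1 and -4.99 to -3.25 for Ptprb.

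Pericyte and mural cell genes had no common direction. Of 21 genes, 3 rose, 3 fell and 15 did not pass, with 3 higher and 4 lower when adjusted over the list alone (median 0.99; adjusted p = 0.95). Pdgfrb, a growth factor receptor of pericytes, rose 9.02-fold and Cox4i2 17.9-fold, while Rgs5, a pericyte marker, fell 21.2-fold and Ebf1, which B cells also express, 8.35-fold. The other lists were not called. Their medians and adjusted p were -0.52 and 0.849 for fibroblast genes, 2.17 and 0.495 for skeletal muscle fibre genes, 1.83 and 0.72 for myogenic progenitor genes, -2.80 and 0.116 for adipocyte genes, 0.68 and 0.517 for macrophage genes, 1.00 and 0.519 for TGF-beta and BMP targets, 0.06 and 0.434 for hypoxia and glycolysis genes, and -0.25 and 0.667 for mitochondrially encoded genes. For interferon response genes the median of 0.20 and mean of 0.11 were positive while the test pointed down (adjusted p = 0.729). Within these lists the fibroblast gene Fap rose 29.3-fold, the macrophage complement gene C1qa 5-fold and the collagen-modifying enzyme P4ha2 3.97-fold, the lipase gene Lpl fell 25.8-fold, and Des and Acta1 of muscle were at 50.3 ± 70.7 and 432 ± 605 CPM against 11.9 ± 8.61 and 57.4 ± 11.0 CPM (adjusted p = 0.448 and 0.346). Acta1 had 3.77 and 859 CPM in osteosarcoma replicates 1 and 2, and without replicate 2 the log2 fold changes of Des and Acta1 were -5.12 and -3.93. When each library was left out in turn, the log2 fold changes ranged from 1.97 to 3.79 for Pdgfrb, 3.09 to 4.76 for Cox4i2, -5.89 to -3.72 for Rgs5, -3.57 to -2.28 for Ebf1, 4.43 to 5.50 for Fap and 1.57 to 2.80 for C1qa.

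In all, 1992 genes were higher and 2094 lower in osteosarcoma than in NG2 cells (edgeR quasi-likelihood, adjusted p under 0.05), 1263 and 1542 of them by at least 4-fold, and the libraries of the groups did not overlap for 65.1% of the 19024 genes, where chance gives 33.3%. The counts fell to 673 higher and 824 lower without NG2 cell replicate 1, 598 and 745 without NG2 cell replicate 2, 705 and 1003 without soft tissue sarcoma replicate 1, and 684 and 1055 without soft tissue sarcoma replicate 2. The chondrocyte list was no longer called without NG2 cell replicate 2 (adjusted p = 0.21) or soft tissue sarcoma replicate 1 (0.0642), and osteoclast genes without osteosarcoma replicate 2 (0.0724). The same held for secreted Wnt antagonists without NG2 cell replicate 2 (0.0658) or soft tissue sarcoma replicate 1 (0.0587), and p53 targets without NG2 cell replicate 2 (0.0558) or osteosarcoma replicate 1 (0.0634). Without osteosarcoma replicate 1 the pericyte and muscle fibre lists were called as higher (adjusted p = 0.0147 and 0.000116), and without osteosarcoma replicate 2 as lower (0.0188 and 0.0423), when fibroblast and interferon response genes were called as lower too (0.0372 and 0.00135). Of the 68 called genes named for this comparison, 38 stayed called without NG2 cell replicate 1, 38 without NG2 cell replicate 2, 54 and 55 without the soft tissue sarcoma replicates 1 and 2, and 63 without either osteosarcoma library, and every one of them kept its sign. Kept signs were favoured, since each fit reused libraries from which the genes had been called. The fold changes of 42 of these 68 genes moved by over 1.5 times in at least 1 of these fits. With no library of the compared groups left out, a model of only these groups called 733 genes higher and 1175 lower. The replicate block called 1247 and 1413, and DESeq2 3363 and 3531.

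**Figure D3:**
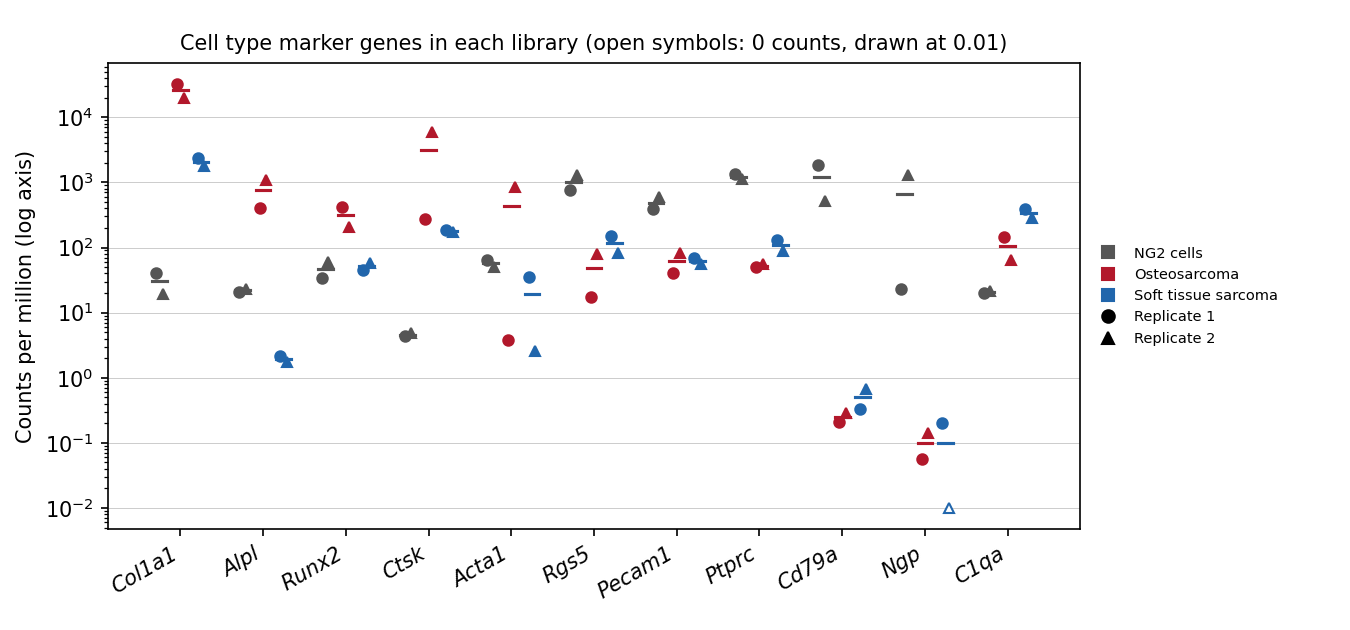
CPM (normalised read counts, log axis) of cell type marker genes in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2, bars for means of 2 libraries, and an open symbol for a library at 0 counts. Cd79a was at 524 CPM or more in NG2 cells and at most 0.674 CPM in tumours, and Ctsk differed between the osteosarcomas (276 and 6020 CPM).

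Soft tissue sarcomas were compared with NG2 cells for the same purpose. Among genes with at least 10 counts in the lower group and the other limits of the naming rule, the largest rises were in Crabp1 (ENSMUSG00000032291; chromosome 9, 54764748 to 54773110), a retinoic acid binding protein, at 800 ± 736 CPM (SD, n = 2) against 0.249 ± 0.353 CPM, and in Wnt5a, a ligand of non-canonical Wnt signalling, at 111 ± 31.5 CPM against 0.263 ± 0.372 CPM. Dkk2, a secreted Wnt antagonist, rose 306-fold, though from 463 ± 380 CPM in unequal tumours, and the collagen and collagen receptor genes Col7a1 and Mrc2 rose by log2 fold changes of 8.25 ± 1.22 and 8.02 ± 0.86 (SE). The largest falls under the rule were again in blood cell genes: Cd79a fell from 1197 ± 952 to 0.505 ± 0.239 CPM and Ngp from 661 ± 902 to 0.101 ± 0.142 CPM. Steap2, Tfap2a and Adamts14 completed the largest rises under the rule at log2 fold changes of 8.54, 7.92 and 7.91, and Fcer2a, Ccr7, Cd69, Elane and Jchain were also among the largest falls, from -10.47 for Fcer2a to -10.07 for Jchain, which joins the chains of secreted antibodies. With each library left out, the log2 fold changes ranged from 10.17 to 12.36 for Crabp1, 7.71 to 8.97 for Wnt5a, 7.01 to 9.50 for Dkk2, 7.40 to 8.29 for Col7a1, 7.19 to 9.90 for Mrc2, -11.89 to -10.04 for Cd79a, -13.34 to -7.65 for Ngp, 7.49 to 8.69 for Steap2, 6.53 to 8.59 for Tfap2a, 6.98 to 8.15 for Adamts14, -11.10 to -9.34 for Fcer2a, -10.79 to -9.51 for Ccr7, -12.13 to -9.59 for Cd69, -11.07 to -5.82 for Elane and -10.91 to -7.72 for Jchain.

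The lists of matrix, bone, cell cycle and hypoxia genes were called as higher. In the matrix remodelling list 15 of 26 genes rose and 11 did not pass, and all 26 were higher when adjusted over the list alone. The matrix remodelling list had a median log2 fold change of 5.13 (adjusted p = 6.11e-16, and adjusted p = 0.313 with an estimated correlation). Bgn rose 22.5-fold, Col5a2 37.4-fold and Loxl3, a collagen crosslinking enzyme, 66.7-fold. Of 25 osteoblast and bone matrix genes, 5 rose, 1 fell and 19 did not pass, with the same numbers when adjusted over the list alone. The osteoblast and bone matrix list had a median log2 fold change of 0.49, or 0.18 with genes at 0 counts at their bounds, (adjusted p = 0.0327, and adjusted p = 0.534 with an estimated correlation). Col1a1 rose 69.0-fold, Col1a2 35.3-fold and Sparc 6.52-fold, all of which connective tissue cells also express, while Alpl fell 11.2-fold, Runx2 was at 51.5 ± 8.65 CPM against 47.1 ± 18.8 CPM (adjusted p = 0.862), and Sp7 had 0 counts in both libraries. Cell cycle genes rose in 20 of 30 cases and 10 did not pass, with 22 higher when adjusted over the list alone. The cell cycle list had a median log2 fold change of 1.93 (adjusted p = 7.14e-12, and adjusted p = 0.348 with an estimated correlation). Cdc20 rose 15.5-fold, Plk1 33.6-fold and Top2a 3.54-fold, and Mki67 was at 97.9 ± 4.65 CPM against 48.0 ± 29.2 CPM (adjusted p = 0.201). Of 18 hypoxia and glycolysis genes, 10 rose and 8 did not pass, with 10 higher and 1 lower when adjusted over the list alone. The hypoxia and glycolysis list had a median log2 fold change of 1.75 (adjusted p = 6.35e-05, and adjusted p = 0.348 with an estimated correlation). The glycolytic enzyme gene Pgk1 rose 6.72-fold and the glucose transporter gene Slc2a1 6.03-fold. Without 1 library at a time, log2 fold changes ranged from 5.22 to 6.56 for Loxl3, 5.66 to 6.78 for Col1a1, 3.53 to 4.55 for Cdc20, 4.56 to 5.86 for Plk1 and 1.88 to 3.05 for Slc2a1.

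The macrophage list was called as higher, and the lymphocyte, granulocyte and erythroid, endothelial, Schwann cell and adipocyte lists as lower. Of 18 macrophage genes, 5 rose and 13 did not pass, with 5 higher when adjusted over the list alone. The macrophage list had a median log2 fold change of 1.5 (adjusted p = 0.000724, and adjusted p = 0.438 with an estimated correlation). C1qa rose 16.1-fold, C1qb 14.1-fold and Csf1r, the receptor for a macrophage growth factor, 5.20-fold. Of 15 lymphocyte genes, 11 fell and 4 did not pass, with 11 lower when adjusted over the list alone. The lymphocyte list had a median log2 fold change of -5.23 (adjusted p = 1.95e-12, and adjusted p = 0.134 with an estimated correlation). Lck fell 21.6-fold, the T cell gene Cd2 139-fold and Ptprc 11.2-fold. Granulocyte and erythroid genes fell in 3 of 16 cases and 13 did not pass, with 7 lower when adjusted over the list alone. The granulocyte and erythroid list had a median log2 fold change of -4.20 (adjusted p = 0.0198, and adjusted p = 0.48 with an estimated correlation). Elane, a neutrophil protease gene, fell 1110-fold, but had 8.81 and 373 CPM in NG2 cell replicates 1 and 2, and its log2 fold change without replicate 2 was -5.82. Of 16 endothelial genes, 7 fell and 9 did not pass, with 11 lower when adjusted over the list alone. The endothelial list had a median log2 fold change of -2.27 (adjusted p = 6.35e-05, and adjusted p = 0.534 with an estimated correlation). Pecam1 fell 7.72-fold and Sox17, an endothelial transcription factor, 17.5-fold. Of 11 Schwann cell and glia genes, 6 fell and 5 did not pass, with 7 lower when adjusted over the list alone. The Schwann cell and glia list had a median log2 fold change of -4.23 (adjusted p = 2.67e-06, and adjusted p = 0.348 with an estimated correlation). Foxd3, a transcription factor of neural crest cells, fell at least 141-fold. Of 13 adipocyte genes, 8 were tested, and Adipoq, Plin1, Lep, Cidec and Cidea were not among them. Of the 8 tested genes, 3 fell and 5 did not pass, with 5 lower when adjusted over the list alone. The adipocyte list had a median log2 fold change of -3.25 (adjusted p = 0.00226, and adjusted p = 0.313 with an estimated correlation). Lpl fell 116-fold and Fabp4, a fatty acid binding protein gene, 21.9-fold. Leaving out single libraries, log2 values ranged from -8.15 to -6.50 for Cd2, -4.64 to -3.29 for Sox17, -7.83 to -6.32 for Lpl and -5.01 to -3.86 for Fabp4.

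The lists of p53 targets and of immediate early and heat shock genes were also called as lower. Of 24 p53 targets, 2 rose, 7 fell and 15 did not pass, with 2 higher and 8 lower when adjusted over the list alone. The p53 targets list had a median log2 fold change of -0.72 (adjusted p = 0.0126, and adjusted p = 0.348 with an estimated correlation). Btg2 fell 35.1-fold, Pmaip1 40.8-fold, Cdkn1a 4.63-fold and Mdm2, the gene of the p53 ubiquitin ligase, 2.60-fold. Of 22 immediate early and heat shock genes, 19 fell and 3 did not pass, with 20 lower when adjusted over the list alone. The immediate early and heat shock list had a median log2 fold change of -4.29 (adjusted p = 3.97e-26, and adjusted p = 0.134 with an estimated correlation). Klf2 fell 53.4-fold, Junb 18.6-fold and Jund 16.8-fold, again against cells that alone had been sorted. For both lists, sorting and other cell types in the NG2 cell libraries cannot be separated from the group.

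Other lists were not called. Among 28 Wnt ligands and receptors, 3 rose, 1 fell and 24 did not pass (median 1.38, or 0.92 with bounds; adjusted p = 0.053), and Fzd2 rose 7.61-fold. Among 13 secreted Wnt antagonists, 4 rose, 3 fell and 6 did not pass (median 1.79; adjusted p = 0.359), and Sfrp2 rose at least 1220-fold and Dkk3 111-fold, while Sfrp5 had 37.7 ± 0.25 CPM in NG2 cells and 0.0169 ± 0.0238 CPM in the tumours. For Wnt/beta-catenin targets the median and mean were 0 while the test pointed up (adjusted p = 0.934), with Ccnd1 higher 15.8-fold and Lef1 and Tcf7, transcription factors that T cells also express, lower 17.9-fold and 14.7-fold. Medians and adjusted p were -1.62 and 0.76 for chondrocyte genes (median -0.55 with bounds), 0.78 and 0.589 for osteoclast genes, 1.29 and 0.182 for fibroblast genes, -1.60 and 0.129 for muscle fibre genes, -2.26 and 0.0796 for myogenic progenitor genes, 0.78 and 0.425 for TGF-beta and BMP targets, -0.89 and 0.0528 for mitochondrially encoded genes, and 0.78 and 0.141 for the Hox clusters. The pericyte list had a median of 0.02, a mean of -0.26 and a test that pointed down (adjusted p = 0.849), and the interferon list a median of 0.09, a mean of -0.02 and a test that pointed down (adjusted p = 0.794). Within these lists Rgs5 fell 8.86-fold and Myh11, a smooth muscle myosin, 30.4-fold, Pax7, a muscle stem cell factor with 5.63 ± 4.32 CPM in NG2 cells, fell at least 168-fold, Hoxc8 rose 76.3-fold and the cell cycle inhibitor gene Cdkn2b 41.4-fold. With each library left out, the log2 fold changes ranged from 5.40 to 7.44 for Dkk3, 2.88 to 4.56 for Ccnd1, -5.17 to -3.58 for Lef1, -4.37 to -3.07 for Tcf7, -5.33 to -4.34 for Myh11 and 4.88 to 6.12 for Cdkn2b.

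In total, 1882 genes were higher and 1789 lower (edgeR quasi-likelihood, adjusted p under 0.05), 1191 and 1251 of them by at least 4-fold, and the groups did not overlap for 70.4% of genes, where chance gives 33.3%. Without soft tissue sarcoma replicate 1 or replicate 2, edgeR called 0 genes (4611 and 4372 genes at an unadjusted p under 0.05, smallest adjusted p 0.0679 and 0.0649). There DESeq2 called 1617 higher and 1978 lower, and 1492 higher and 1843 lower. Without NG2 cell replicate 1 or 2 edgeR called 388 higher and 405 lower, and 364 higher and 427 lower. Of the 59 called genes named for this comparison, 31 and 29 stayed called without NG2 cell replicates 1 and 2, all 59 without either osteosarcoma, and none by edgeR without either soft tissue sarcoma, and the fold changes of 33 moved by over 1.5 times in at least 1 of these fits. Calls of lists ended without NG2 cell replicate 1 for osteoblast genes (adjusted p = 0.0742) and macrophage genes (0.0742), and without NG2 cell replicate 2 for p53 targets (0.0658). They ended without soft tissue sarcoma replicate 1 for osteoblast genes (0.079), granulocyte genes (0.0953) and p53 targets (0.0719). Wnt ligands became called without NG2 cell replicate 1 (0.0249), osteosarcoma replicate 1 (0.0251), osteosarcoma replicate 2 (0.0288) and soft tissue sarcoma replicate 2 (0.0192). Mitochondrial genes became called without NG2 cell replicate 2 (0.0361), osteosarcoma replicate 1 (0.0159), osteosarcoma replicate 2 (0.0186) and soft tissue sarcoma replicate 2 (0.0259), and Hox genes without NG2 cell replicate 2 (0.0458). Muscle fibre genes became called without osteosarcoma replicate 1 (0.0227), osteosarcoma replicate 2 (0.0372) and soft tissue sarcoma replicate 1 (0.0188). Fibroblast genes became called without osteosarcoma replicate 1 (0.0187) and replicate 2 (0.0212), and myogenic progenitor genes without soft tissue sarcoma replicate 1 (0.0279).

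The tumour types were both compared with the same NG2 cell libraries, to describe what they had in common. Of the called genes, 1232 were higher and 1345 lower in both, where independent lists of these sizes would share 197 and 197. Part of the excess may come from the shared controls. A split would have left 1 control library per tumour type and was not made. Across the 19024 genes, the log2 fold changes of both comparisons correlated with r = 0.768, and their covariance was 7.30. In simulations that drew unchanged tumours and shared controls alike from the NG2 cell means, these were 0.503 and 0.686, a difference of 6.61 in covariance. The simulations called 0 genes as higher and 0 as lower in both. No gene was changed in them, so this does not measure the excess of shared calls. The log2 fold changes had the same sign for 80.7% of genes, against 66.4% in the simulations. Genes higher in both included Col1a1, Col5a2, Cdk1, Plk1 and Sfrp2, and genes lower in both included Btg2, Atf3 and Pecam1. Only the NG2 cells had been sorted. What the tumour types shared against them can therefore not be separated from sorting, tissue or any other cell types in the NG2 cell libraries. Without NG2 cell replicate 1 or 2 the genes higher in both were 311 and 281 and those lower in both 345 and 359, and without either soft tissue sarcoma library they were 0, since edgeR then called 0 genes in soft tissue sarcoma (4611 and 4372 at an unadjusted p under 0.05). Calls went in opposite directions for 21 genes.

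Soft tissue sarcomas and osteosarcomas were compared to ask which genes separated the tumour types. Fez1 (ENSMUSG00000032118; chromosome 9, 36821864 to 36878924), a gene best known from neurons, was the largest rise in soft tissue sarcoma among genes that met the naming rule, with at least 10 counts in the lower group, at 110 ± 40.2 CPM (SD, n = 2) against 0.798 ± 0.0231 CPM (log2 fold change 7.09 ± 0.46 SE, edgeR adjusted p = 0.0428). Pdpn, the gene of the membrane glycoprotein podoplanin, rose 51.5-fold, Fosl1, an AP-1 transcription factor, 36.4-fold, Tbx3, a T-box transcription factor, 33.5-fold, and the monocyte-attracting chemokines Ccl2 and Ccl7 rose 16-fold and 12.2-fold. Alpl (ENSMUSG00000028766; chromosome 4, 137741733 to 137796384) was the largest fall under the same rule, at 1.95 ± 0.327 CPM in soft tissue sarcoma against 755 ± 492 CPM in osteosarcoma (log2 fold change -8.59 ± 0.67, adjusted p = 0.0428). The secreted glutathione peroxidase gene Gpx3 fell 28.8-fold, Wnt4 24.9-fold, the collagen gene Col22a1 132-fold and Btla, a receptor of lymphocytes, 109-fold. The fall of Btla ran against the lymphocyte list, which was higher in soft tissue sarcoma than in osteosarcoma (median log2 fold change 2.99). Glipr2 and Basp1 rose 17.8-fold and 15.9-fold, and Adam23 and Fam102a, the last of the 7 falls that met the rule, fell 25.4-fold and 9.31-fold. With 1 library left out, the log2 fold changes ranged from -9.12 to -7.69 for Alpl, -7.60 to -6.14 for Col22a1 and -7.69 to -6.26 for Btla.

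Bone genes were lower in soft tissue sarcoma as a list, though few passed singly. Of 25 osteoblast and bone matrix genes, 1 fell and 24 did not pass, with 23 lower when adjusted over the list alone. The osteoblast and bone matrix list had a median log2 fold change of -5.96 (adjusted p = 2.18e-35, and adjusted p = 0.134 with an estimated correlation). Sp7 had 109 ± 34.95 CPM in osteosarcoma and 0 counts in soft tissue sarcoma (adjusted p = 0.0583), Runx2 316 ± 154 against 51.5 ± 8.65 CPM (0.0984) and Col1a1 25900 ± 8911 against 2084 ± 431 CPM (0.0731). None of the 14 chondrocyte genes passed, and 6 were lower when adjusted over the list alone. The chondrocyte list had a median log2 fold change of -4.16 (adjusted p = 9.1e-06, and adjusted p = 0.299 with an estimated correlation). Col11a2 was at 254 ± 326 CPM in osteosarcoma against 0.294 ± 0.0603 CPM. For 14 osteoclast genes, where Acp5 was at 3930 ± 4999 against 56.2 ± 46.0 CPM, the number lower was 7 when adjusted over the list alone. The osteoclast list had a median log2 fold change of -3.95 (adjusted p = 1.39e-05, and adjusted p = 0.48 with an estimated correlation). Of 20 muscle fibre genes, with Acta1 at 432 ± 605 against 19.0 ± 23.2 CPM, none passed by either adjustment. The skeletal muscle fibre list had a median log2 fold change of -3.75, or -3.71 with genes at 0 counts at their bounds, (adjusted p = 0.000302, and adjusted p = 0.55 with an estimated correlation). Of 12 myogenic progenitor genes, 2 were lower when adjusted over the list alone. The myogenic progenitor list had a median log2 fold change of -3.38 (adjusted p = 0.00245, and adjusted p = 0.318 with an estimated correlation). Cdh15, a cadherin of myoblasts, had 44.5 ± 1.03 CPM in osteosarcoma and 0 counts in soft tissue sarcoma (adjusted p = 0.0666). The 8 adipocyte genes had a median of -2.02 (adjusted p = 0.025, and adjusted p = 0.335 with an estimated correlation), and 2 were lower when adjusted over the list alone. Among them Car3, a carbonic anhydrase of fat and muscle, was at 332 ± 296 CPM in osteosarcoma against 0.395 ± 0.272 CPM. The 11 Schwann cell genes had a median of -0.96, or -0.74 with bounds (adjusted p = 0.0263, and adjusted p = 0.534 with an estimated correlation). The 12 mitochondrially encoded genes had a median of -0.57 (adjusted p = 0.0245, and adjusted p = 0.55 with an estimated correlation), or -0.62 (adjusted p = 0.0228) without 4 members of at most 5.26 CPM, with mt-Nd2 at 989 ± 268 CPM in osteosarcoma against 589 ± 7.14 CPM. For 13 secreted Wnt antagonists, 2 were higher and 4 lower when adjusted over the list alone. The secreted Wnt antagonists list had a median log2 fold change of -2.46 (adjusted p = 0.0245, and adjusted p = 0.335 with an estimated correlation). Dkk2 was at 463 ± 380 against 1.82 ± 2.20 CPM, Sfrp1 at 0.412 ± 0.322 against 9.72 ± 0.0798 CPM, and Wif1 at 200 ± 199 CPM in osteosarcoma against 0.00839 ± 0.0119 CPM.

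Lists that were higher in soft tissue sarcoma held no gene past the threshold over all genes. For 18 hypoxia and glycolysis genes, 5 were higher when adjusted over the list alone. The hypoxia and glycolysis list had a median log2 fold change of 0.88 (adjusted p = 3.65e-06, and adjusted p = 0.335 with an estimated correlation). Slc2a1 was at 212 ± 113 against 17.5 ± 3.38 CPM and Adm, a vasodilator peptide gene, at 51.5 ± 2.99 against 4.33 ± 0.844 CPM (both adjusted p = 0.0583). For 15 lymphocyte genes, 4 were higher when adjusted over the list alone. The lymphocyte list had a median log2 fold change of 2.99, or 2.98 with genes at 0 counts at their bounds, (adjusted p = 3.66e-08, and adjusted p = 0.299 with an estimated correlation). Levels were low, with Lck at 11.3 ± 2.04 against 2.36 ± 0.12 CPM. The macrophage list had a median of 1.80 (adjusted p = 7.02e-06, and adjusted p = 0.348 with an estimated correlation), with C1qa at 336 ± 72.8 against 104 ± 57.6 CPM. The fibroblast list had a median of 1.24 (adjusted p = 0.0259, and adjusted p = 0.534 with an estimated correlation). Its gene Dpt, which encodes a dermal matrix protein, was at 252.1 CPM against 13.5 CPM, while 1 gene, Fap, was lower when adjusted over the list alone. The granulocyte and erythroid list had a median of 2.53, or 2.17 with bounds (adjusted p = 0.0263, and adjusted p = 0.493 with an estimated correlation). The haemoglobin genes Hba-a1 and Hbb-bs, near-identical to other copies, were at 126 ± 128 and 154 ± 159 against 19.1 ± 14.8 and 25.3 ± 19.6 CPM.

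Medians and adjusted p of the lists that were not called were -0.32 and 0.779 for pericyte genes, -0.26 and 0.517 for endothelial genes, -0.09 and 0.0812 for Wnt/beta-catenin targets, -0.41 and 0.116 for Wnt ligands and receptors, 0.24 and 0.665 for TGF-beta and BMP targets, 0.51 and 0.116 for immediate early and heat shock genes, and -0.54 and 0.232 for the Hox clusters. The sign of median, mean and test differed for p53 targets (-0.27, 0.01 and down; adjusted p = 0.975), cell cycle genes (0.07, -0.09 and down; 0.674), matrix remodelling genes (0.20, -0.19 and up; 0.853) and interferon response genes (-0.19, -0.13 and up; 0.909). Within the matrix list Mmp13 was at 40.5 ± 6.41 CPM in soft tissue sarcoma against 14510 ± 13120 CPM in osteosarcoma (adjusted p = 0.0984), and Vcan, a large proteoglycan gene, at 263 ± 20.2 against 24.3 ± 18.6 CPM (adjusted p = 0.109). None of the 3 comparisons kept a list call with an estimated correlation (smallest adjusted p 0.134; 4, 4 and 3 lists at an unadjusted p under 0.05).

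Between the tumour types 16 genes were higher and 11 lower in soft tissue sarcoma (edgeR quasi-likelihood, adjusted p under 0.05), 3022 genes had an unadjusted p under 0.05, and DESeq2 called 1144 higher and 772 lower. An edgeR model of only these 2 groups called 0 genes (smallest adjusted p 0.0533), and the replicate block 4 higher and 4 lower. The libraries did not overlap for 50.3% of genes, where chance gives 33.3%. Without NG2 cell replicate 1 or 2, or soft tissue sarcoma replicate 1 or 2, edgeR called 0 genes (3055, 3064, 1573 and 1594 at an unadjusted p under 0.05). There DESeq2 called 1177 higher and 784 lower, 1179 and 789, 370 and 342, and 429 and 328. Without osteosarcoma replicate 1 edgeR called 22 higher and 36 lower, and without osteosarcoma replicate 2 178 and 127. Of the 16 called genes named, 12 stayed called without osteosarcoma replicate 1 and all 16 without replicate 2. Several list calls ended without osteosarcoma replicate 2: osteoclast (adjusted p = 0.0658), muscle fibre (0.576, direction turned), myogenic progenitor (0.328), adipocyte (0.0724), granulocyte (0.0779), Schwann cell (0.513), Wnt antagonists (0.0779) and mitochondrial genes (0.194). Without NG2 cell replicates 1 and 2 they ended for fibroblast (0.0571 and 0.0518), adipocyte (0.111 and 0.114), Schwann cell (0.0517 and 0.0556) and Wnt antagonist genes (0.111 and 0.114). They ended without osteosarcoma replicate 1 for fibroblast (0.0601) and granulocyte genes (0.0788). They also ended without soft tissue sarcoma replicate 1 for fibroblast (0.0807), Schwann cell (0.0719) and mitochondrial genes (0.0807), and without soft tissue sarcoma replicate 2 for granulocyte (0.11) and Wnt antagonist genes (0.0644). Lists became called, with direction turned between the osteosarcoma libraries, without osteosarcoma replicate 1 and 2 for pericyte (0.000136 and 0.000483), endothelial (0.000137 and 0.0193), cell cycle (0.0474 and 0.00834), matrix (0.0015 and 4.03e-06) and interferon genes (0.000713 and 2.15e-05). Further lists became called without osteosarcoma replicate 2 for Wnt/beta-catenin targets (0.0193), and without soft tissue sarcoma replicate 2 for immediate early (0.00622) and Hox genes (0.0189).

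**Figure D4:**
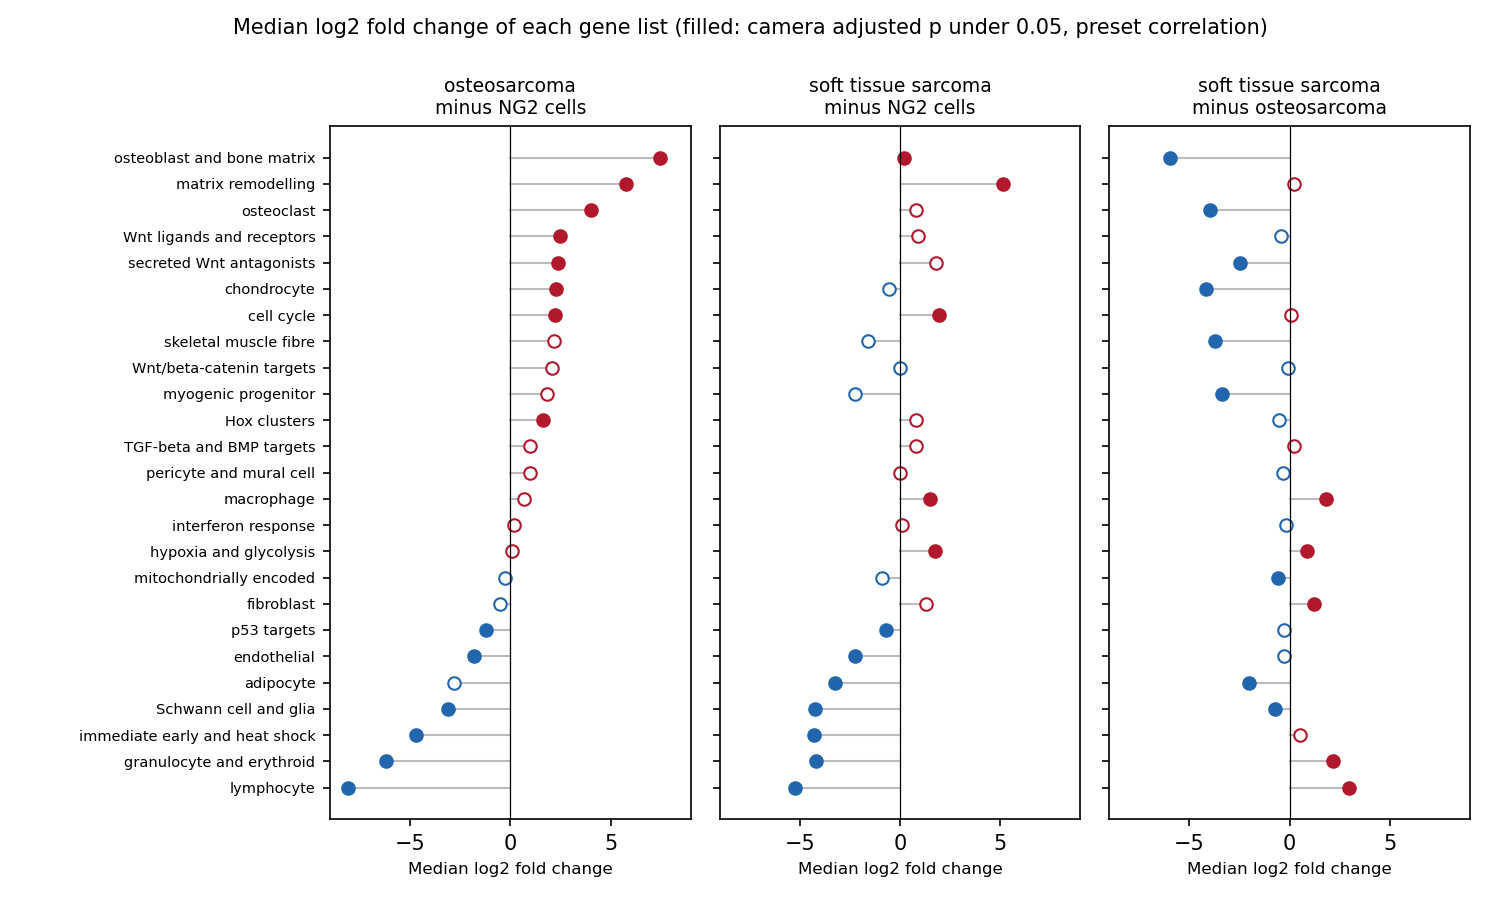
Median log2 fold change of the 25 gene lists in the 3 comparisons, with genes at 0 counts in a group set to their bounds. Filled points had a camera adjusted p under 0.05 at the preset correlation, and osteoblast and bone matrix genes had the largest median in osteosarcoma (7.46) and the lowest between the tumour types (-5.96).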

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

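The tests weighed for the other cell types, the sex-linked genes and the osteoclast and muscle genes were all chosen only after those results were seen. The test of the difference between the tumour types was planned.

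The 27 genes called between the tumour types drew attention because the effect against the same NG2 cells differed between osteosarcoma and soft tissue sarcoma, by the direct test of soft tissue sarcoma minus osteosarcoma. For 11 of them the calls against NG2 cells went in opposite directions. In this group the log2 fold changes between the tumour types were 11.18 for Efemp1, 7.09 for Fez1, 5.69 for Pdpn, 4 for Ccl2, 3.99 for Basp1, 3.6 for Ccl7, -8.59 for Alpl and -10.57 for Insc. The other 3 had at most 3 counts in 1 tumour type, so their mean level in the higher type is given: Acpp reached 207 CPM in soft tissue sarcoma, Ppfia2 46.9 CPM and Kcnk1 76.7 CPM in osteosarcoma. The remaining genes higher in soft tissue sarcoma had log2 fold changes of 5.68 for Serpini1, 5.18 for Fosl1, 5.07 for Tbx3, 4.16 for Glipr2, 3.46 for Rgs16, 3.25 for Ctsl, 3.15 for Adcy7, 2.77 for Vcam1 and 2.59 for Prkacb. The remaining lower genes had -3.22 for Fam102a, -4.64 for Wnt4, -4.67 for Adam23, -4.85 for Gpx3, -6.77 for Btla, -7.05 for Col22a1 and -10.24 for Xist. Without NG2 cell replicate 1 or 2 or soft tissue sarcoma replicate 1 or 2, edgeR called 0 genes between the tumour types (3055, 3064, 1573 and 1594 at an unadjusted p under 0.05), where DESeq2 called 1177 higher and 784 lower, 1179 and 789, 370 and 342, and 429 and 328. By the lane in the deposited names, each tumour type had a lane of its own, so these differences and a lane effect cannot be told apart. Both osteosarcomas had Xist, while both soft tissue sarcomas had Y-linked transcripts and nearly no Xist. A difference in sex is therefore not separated from the tumour type either.

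Transcripts of lymphocytes, granulocytes and endothelium were abundant in the NG2 cell libraries and unequal between them: in replicates 1 and 2, Cd79a had 1870 and 524 CPM, Lck 195 and 293 CPM, Ngp 23.1 and 1300 CPM and Pecam1 384 and 592 CPM. For B cell genes, reads exchanged from the tumour libraries are argued against, since 100% of 18 genes were lower in every tumour library than in both NG2 cell libraries. This restates part of the pattern, and genes of the other cell types were not tested in this way. Some of those, such as Mpo and Cldn5, were higher in the osteosarcomas than in NG2 cell replicate 1. Cells or RNA of other types stay a candidate explanation: of 4 marker lists, which share 0 genes with the other lists, 3 had a median log2 ratio of replicate 2 to replicate 1 outside the range of matched random lists (B cell -1.41 against -0.72 to 0.44, granulocyte precursor 5.6 against -0.74 to 0.92, endothelial 0.91 against -0.71 to 0.62), while T cell genes, at 0.58, lay inside theirs (-0.61 to 0.65), as did pericyte genes, at 0.3 (-0.67 to 1.02). That criterion was added after a first one, a small spread of the ratios within each list, had held for 1 of the 4 lists only. Regulation of these genes would shift the medians too, so the ratios cannot decide and the explanation stays open. Leukocyte transcripts were a large part of these libraries whatever their source. Ptprc averaged 1230 ± 139.4 CPM there and Cspg4, the gene of the sort marker, 34.65 ± 5.656 CPM. Immunoglobulin genes held 0.974% and 5.1% of the counts of replicates 1 and 2. The sort for NG2 should remove such cells, its purity is not given, and only these libraries were sorted, so sorting, tissue and group cannot be told apart.

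Osteosarcoma replicate 1 carried Y-linked genes together with Xist. Reads exchanged from the soft tissue sarcoma libraries are argued against: over 16 genes abundant in soft tissue sarcoma and nearly absent from osteosarcoma replicate 2, the median level in replicate 1 was 0.0433% of that in soft tissue sarcoma, while the Y-linked genes stood at 19.6% to 26.4%. Reads of X-linked homologues are argued against by the highest Y-linked level in the 3 other libraries with Xist, 0.0711 CPM. RNA of male and female animals in 1 library is a candidate explanation: the log2 ratios of the 4 Y-linked genes to soft tissue sarcoma had an SD of 0.21, at percentile 2.24 of random lists of 4 genes (median SD 0.87). The small SD would also follow from Y-linked expression in only part of the cells of 1 animal, so it does not single out a mixture. Such partial expression alone would not account for Xist, which averaged 0.1093 ± 0.03599 CPM in the soft tissue sarcomas with their Y-linked transcripts. The labels give no sex, and no biological explanation was tested.

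Of the osteoclast genes, 14 of 14, and of the muscle fibre genes, 18 of 19, were higher in osteosarcoma replicate 2 (lumbar spine) than in replicate 1 (right tibia), with Acp5 at 7460 and 395 CPM and Ttn at 270 and 3.37 CPM. Amplification noise that acts on each gene separately is argued against by the median log2 ratio of the osteoclast list, 4.34, where matched random lists gave -0.85 to 0.77. Other cell types in different shares in the pair of libraries stay open: the medians of 2 of 2 lists, 1 osteoclast gene of which is also in another list, lay outside their random ranges (muscle fibre 5.91 against -1.02 to 2.19), but this restates the pattern and regulation of these genes would give it too, and a small spread within a list, the criterion tried first, held for neither (percentiles 74.1 and 75.1). The site of the tumour, with 1 library each, remains an untested biological explanation, and of 25 osteoblast genes 20 were lower and 5 higher in replicate 2, Ibsp among the higher ones (439 and 17600 CPM), with a median ratio of -1.76.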

How the results depend on the processing

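Removal of immunoglobulin genes, removal of 4 genes of low counts from the mitochondrial list, the newer quasi-likelihood method and the DESeq2 counts beside left-out libraries were chosen only after the data had been seen; the other alternatives were planned. With 1 library left out, the lone sample of its group is assumed to vary like the other groups. The cause of a change was not tested except where fewer libraries or genes entered a fit.

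Of the counts of called genes under the alternatives, 66 stayed within 1.5 times the reported count and 60 did not. DESeq2 called 3363 genes higher and 3531 lower in osteosarcoma than in NG2 cells, 3153 and 3286 in soft tissue sarcoma, 2192 and 2391 in both, and 1144 and 772 between the tumour types. A model of only the 2 groups compared called 733 higher and 1175 lower in osteosarcoma. Between the tumour types it called 0 and 0 (edgeR; 3126 genes at an unadjusted p under 0.05, smallest adjusted p 0.0533). There, no filter gave 247 and 162, at least 50 counts 53 and 32, and the newer quasi-likelihood method 156 and 111.

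The replicate numbers did not pair the libraries: the correlation of deviations was 0.049 between NG2 cells and osteosarcoma, -0.003 between NG2 cells and soft tissue sarcoma, and -0.086 between the tumour types. With the replicate block, 1247 genes were higher in osteosarcoma (1413 lower), 1105 higher and 1104 lower in soft tissue sarcoma, 708 higher and 854 lower in both, and 4 higher and 4 lower between the tumour types. The block ended the calls of chondrocyte genes in osteosarcoma (adjusted p = 0.0936; 0.00849 to 0.438 over the alternatives), osteoblast genes in soft tissue sarcoma (0.0782; 0.0129 to 0.534) and, between the tumour types, myogenic progenitor (0.0553; 5.93e-05 to 0.328), adipocyte (0.0653, 0.0119 to 0.335), granulocyte (0.0653, 0.000806 to 0.493) and Wnt antagonist genes (0.0669, 0.00196 to 0.335). It added mitochondrial genes in soft tissue sarcoma (0.0171, range 0.0159 to 0.58) and changed no other list call. Of the 68, 59 and 16 called genes named in the comparisons, 62, 49 and 4 stayed called with the block.

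Leaving out each library in turn gave 598 to 1636 genes higher and 745 to 1906 lower in osteosarcoma, 0 to 2445 higher and 0 to 2648 lower in soft tissue sarcoma, 0 to 1168 higher and 0 to 1389 lower in both, and 0 to 178 higher and 0 to 127 lower between the tumour types. The counts of 0 came from edgeR without either soft tissue sarcoma library (4611 and 4372 genes at an unadjusted p under 0.05 against NG2 cells, where DESeq2 called 1617 higher and 1978 lower, and 1492 and 1843) and, between the tumour types, from edgeR without either soft tissue sarcoma or either NG2 cell library (1573, 1594, 3055 and 3064 genes at an unadjusted p under 0.05, where DESeq2 called 370, 429, 1177 and 1179 higher). The log2 fold changes of all called genes named in the comparisons kept their sign in each of these fits. Over all called genes the share that kept its sign was 100% when rounded to 3 digits. The genes had been called from libraries that these fits reuse, which favours kept signs, so the share does not measure how robust the calls are.

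Some values turned direction with a library left out. In osteosarcoma against NG2 cells the log2 fold change ranged from -1.39 to 0.92 for Axin2, from -5.12 to 3.10 for Des and from -3.93 to 3.87 for Acta1. In soft tissue sarcoma it ranged from -0.22 to 0.61 for Runx2, and between the tumour types from -7.38 to 2.34 for Acta1. For Sp7 in soft tissue sarcoma it ranged from -5.80 to 0 with no change of sign, and the 0 arose without NG2 cell replicate 1, where the libraries left in both groups had 0 counts. The adjusted p of lists that turned ranged, in osteosarcoma, from 0.0147 to 0.994 for pericyte, 0.0372 to 0.851 for fibroblast, 0.000116 to 0.574 for muscle fibre, 0.111 to 0.714 for myogenic progenitor, 0.0767 to 0.887 for macrophage, 0.00135 to 0.951 for interferon response and 0.192 to 0.971 for mitochondrial genes. In soft tissue sarcoma it ranged from 0.312 to 0.794 for chondrocyte genes, 0.756 to 0.906 for Wnt/beta-catenin targets and 0.359 to 0.893 for interferon response genes. Between the tumour types it ranged from 0.000136 to 0.951 for pericyte, 7.79e-18 to 0.576 for muscle fibre, 0.000137 to 0.838 for endothelial, 0.325 to 0.912 for p53 target, 0.00834 to 0.967 for cell cycle, 4.03e-06 to 0.855 for matrix and 2.15e-05 to 0.899 for interferon response genes.

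Directions that turned under other settings belonged to uncalled lists: pericyte genes in osteosarcoma without immunoglobulin genes (adjusted p = 0.999, range over the alternatives 0.0147 to 0.999), chondrocyte genes and Wnt/beta-catenin targets in soft tissue sarcoma with at least 50 counts (0.967, range 0.312 to 0.968, and 0.882, range 0.756 to 0.997), and p53 targets between the tumour types with total counts (0.999) and with no filter (0.945, range 0.325 to 0.999). With an estimated correlation all 40 list calls ended. Of the list calls, the model of only the 2 groups compared ended 3 calls and added 4, a filter of at least 50 counts ended 2 and added 2, removal of mitochondrial and haemoglobin genes ended 1, DESeq2's size factors added 2, and no filter and removal of immunoglobulin genes added 1 each. Size factors of DESeq2, total counts, and removal of mitochondrial and haemoglobin genes or of immunoglobulin genes kept each count of called genes within 1.5 times the reported one. Under these settings, no filter, at least 50 counts, the newer quasi-likelihood method and DESeq2, all 68, 59 and 16 called genes named in the comparisons stayed called. Of these genes, the model of only the 2 groups compared kept 57, 59 and 0 called, and leaving out each library moved the fold changes of 42, 33 and 4 by over 1.5 times at least once. Without its 4 genes of low counts the mitochondrial list had adjusted p of 0.794 and 0.0812 in osteosarcoma and soft tissue sarcoma (ranges 0.192 to 0.971 and 0.0159 to 0.58) and 0.0228 between the tumour types (0.000715 to 0.55), each on the same side of the threshold. Depth limited genes with few counts, so that levels or bounds were given where a group had at most 3, as for Acpp in osteosarcoma (1 count). With groups of 2 libraries, no test on other splits of the samples was made.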

Other observations

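Cdkn2a, the gene of the tumour suppressors p16 and p19ARF, had 0.0277 and 0.0458 CPM in NG2 cells (3 counts in all), 13.9 and 7.68 CPM in osteosarcoma, and 47.1 and 40.0 CPM in soft tissue sarcoma. Hmga2, a chromatin protein gene of embryonic tissue, had 331 and 120 CPM in soft tissue sarcoma and at most 2.18 CPM in the other libraries. The mesenchymal transcription factor genes Prrx1, Twist1 and Tbx15 were higher in all 4 tumour libraries than in both NG2 cell libraries: the log2 fold changes in osteosarcoma and soft tissue sarcoma were 5.19 and 6.02 for Prrx1, 6 and 5.87 for Twist1, and 4.97 and 7 for Tbx15. The immune checkpoint gene Cd276 was higher likewise (5.83 and 4.92). H2-Aa and Cd74, which act in antigen presentation by MHC class II, were lower in all 4 tumour libraries, with log2 fold changes of -7.09 and -4.18 for H2-Aa and -7.19 and -4.42 for Cd74, and Jchain, a plasma cell gene, had 193 and 1770 CPM in the NG2 cell replicates 1 and 2.

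These genes were all chosen only after their values were seen, no test was made for them beyond those over all genes, and a lane effect and the group cannot be told apart for them either. The deposited counts of mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 were at most 5.26 CPM in every library, beside 3080 to 8070 CPM for mt-Co1. The rule for reads shared between genes is not stated, so these 4 genes were not interpreted singly.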
